A study of Homo sapiens with 6 samples.

How the data were processed

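RNA from 6 cultures was hybridised to 6 human arrays of 54675 probe sets, 3 of parental OVCAR-3 cells and 3 of spheroid-derived stem-like cells. Per the labels' protocols, RNA was isolated with a kit for small samples and labelled with biotin by in vitro transcription, and the series' design text calls the samples of each group replicate cultures. The deposited values are MAS5 signals, a linear intensity for each probe set, made with Affymetrix Expression Console 5.0 per the submitters' processing notes. MAS5 subtracts a local background and a mismatch estimate and can give dim probe sets very small positive values, so that log2 fold changes of dim genes are unstable. The mean of the central 96% of values was 499.9 on every array, which shows that the deposited intensity values had been scaled to a common target on each array. Detection calls and scan dates were not used here. Scaling to a common mean makes all changes relative to the array's total, so that a change in the RNA content of the cells is not visible.

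The values were used as deposited, as log2 of the signal with no offset. Gene symbols came from the platform annotation: 41091 probe sets carried 1 gene symbol, 1801 several and 11721 none, and 62 were controls. No symbol was changed by the update through the RefSeq gene table (assembly GRCh38.p14), and 54 single symbols had no entry in it. The probe set with the highest mean log2 signal over all 6 arrays represented each of 19775 genes, and a gene was tested if that mean reached the 40th percentile of all probe sets that are not controls (log2 5.58, a signal of 47.8), which left 13605 genes. A level of silent genes was set on each array as the 90th percentile of 107 olfactory receptor probe sets. A gene below it on all 3 arrays of a group has only a bound there. Its fold is given as at least the brighter group's mean over the dimmer group's mean of the higher of the array's silent level and the measured value, on the log2 scale, a rule adapted here for arrays without detection calls. After the values were seen, the same bound was also given for genes in the text below the level on 1 or 2 of the 3 arrays.

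Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. With 3 against 3 the smallest two-sided p of an exact permutation test is 0.1, so that such a test cannot pass 0.05 and is given only for RNA quality measures. The 49 gene lists, written before the data were examined, held 1281 members, of which 1177 had a probe set of their own and 1041 were tested. They were tested with camera (preset correlation 0.01, adjusted over the 49 lists), with camera with an estimated correlation and with fry. Genes are named by a rule also fixed beforehand. It takes the 10 largest rises and the 10 largest falls among changed genes whose groups do not overlap and whose brighter mean is at least the median of all tested genes. It passes over symbols taken as placeholders, among them all that start with LOC, FAM or ZNF. It adds up to 3 members with the smallest adjusted p in the direction of each list past the camera threshold and 1 in the opposite direction, and the 2 smallest in each direction in other lists with at least 5 changed members. It also takes a panel of 15 stem cell, epithelial and mesenchymal markers whatever their result. The counts of changed genes, the list tests and the named genes were recomputed under other normalizations, filters, probe set rules, variance models and array weights, with the replicate number as a block, and without each array in turn. Runs of about 50 neighbouring genes were examined after a look at the data, against 1000 shuffles of gene positions, and a fit with each run's median removed (regional centring) was added as an alternative chosen after seeing the data.

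The tests were first run on simulated data made from these arrays, with 200 genes changed by known folds among 13605. The 200 were drawn from genes with a mean signal at or above the median, so that recovery of dimmer genes was not tested. Of these brighter genes the tests recovered 58% of 50 changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold and 8-fold. Of all calls, 3.57% were unchanged genes. In the real data 44.4% of tested genes were called, a far larger share than was changed in the simulation. The Benjamini-Hochberg cutoff depends on that share, so that these recovery rates do not give the sensitivity of the real comparison. The shifted list was called and no other list was. The simulated genes varied independently of each other, whereas the estimated correlation of the hypoxia list in the real data was 0.54. The simulation therefore does not show how often lists are called wrongly where members vary together. The median standard error of a log2 fold change was 0.13. No 2 arrays held identical values. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.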

Results

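Transcript levels were measured on a human expression microarray of 54675 probe sets in 6 cultures of OVCAR-3, an established human ovarian carcinoma cell line that grows attached as an epithelial sheet. The parental group held 3 replicate cultures of the line, grown attached in medium with 10% fetal bovine serum. The spheroid group held 3 replicate cultures of stem-like cells obtained from the same line as floating spheroids on surfaces that cells do not adhere to. Their medium had no serum and contained 0.4% bovine serum albumin, 20 ng/mL EGF, 10 ng/mL bFGF and 5 µg/mL insulin. Attachment, medium and selection as spheroids therefore differed together between the groups, and their effects were not separated in this design. The median signal was between 87.95 and 93.3 units on the 6 arrays, and 55.4% to 58.8% of probe sets lay above the level of silent genes, set for each array from olfactory receptor probe sets. The number of arrays, 3 in each group, limits the precision of every value below. Values are log2 fold changes of spheroid-derived over parental cells with the limma standard error, written as value ± SE (n = 3 cultures per group), and a gene is said to have risen or fallen only where its adjusted p passed 0.05. Of the named genes, 18 kept their direction but lost that call when all probe sets of a gene were averaged, among them ABCA1, ATR, CANX, CD74, KRT19, LIPA, ME1, NAMPT, NDUFA2, RAD51B and SLC39A14. TXNRD1 reversed in that setting and was no longer past the threshold.

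The comparison asks how the stem-like spheroid cells differ in transcript levels from the line they were derived from. Of 13605 genes tested, 6046 changed (44.4%), 3087 higher and 2959 lower in the spheroid-derived cells, and 6999 had an unadjusted p under 0.05. At least 2-fold changes were found for 1607 genes, 852 higher and 755 lower, of which 86 were near the level of silent genes in the lower group and could be bounded only at less than 2-fold. Over all 13605 tested genes, called or not, the 3 values of each group did not overlap for 7401 (54.4%), where chance gives 10%. Arrays correlated with each other at r = 0.941 to 0.949 within a group and 0.914 to 0.924 between groups, across probe sets, which are not independent replicates. The first principal component, which separated the groups, held 75.9% of the variance, and the second held 8.10%. The difference between the 3' and 5' probe sets of the same transcript, a measure of RNA integrity, differed between the groups by 0.06 ± 0.07 on the log2 scale for ACTB and by -0.03 ± 0.02 for GAPDH (exact permutation test, two-sided, p = 0.5 and 0.4, n = 3 per group, smallest possible p = 0.1).

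Marker genes of stem-like ovarian cancer cells did not all move the same way. CD44, the hyaluronan receptor, rose 15.4-fold (3.94 ± 0.11, adjusted p = 2.42e-08), from a mean signal of 251 to 3849. ALDH1A1, a retinaldehyde dehydrogenase, rose 9.61-fold (3.26 ± 0.10). PROM1, which encodes CD133, rose 3.48-fold (1.80 ± 0.17), and the stem cell factor receptor gene KIT rose 3.08-fold (1.62 ± 0.18). SOX2, a pluripotency factor already at a signal of 4186 in the parental cells, rose 1.84-fold (0.88 ± 0.07). NANOG lay below the level of silent genes on all 3 spheroid arrays and on parental replicates 1 and 2. Its difference, near that level, was not past the threshold (-0.24 ± 0.41, adjusted p = 0.676). This value changed sign with array weights (0.023) and without parental replicate 3 (0.10). ABCG2, the drug transporter behind the side population, was below the dimness filter and below the level of silent genes on all 6 arrays. POU5F1 was read only by a probe set shared among 4 gene symbols, with a mean log2 signal of 6.79 in parental and 7.20 in spheroid-derived cells, and was not tested as a gene. Over the whole list of cancer stem cell markers, 8 of 21 tested members were higher and 8 lower. Their median log2 fold change was -0.04, although the mean was 0.65 and camera pointed up (adjusted p = 0.567). Members that fell included ITGB1, the beta-1 integrin (-0.89 ± 0.06), and SOX17, an endoderm and Müllerian transcription factor (-1.09 ± 0.11). Of the pluripotency factors, 2 of 12 tested members were higher and 3 lower (camera adjusted p = 0.362). SOX2 and KLF4 (0.41 ± 0.08) were higher, and lower levels were found for DNMT3B, a DNA methyltransferase (-0.57 ± 0.09), and LIN28B, an inhibitor of let-7 maturation (at least 9.77-fold lower).

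**Figure D1:**
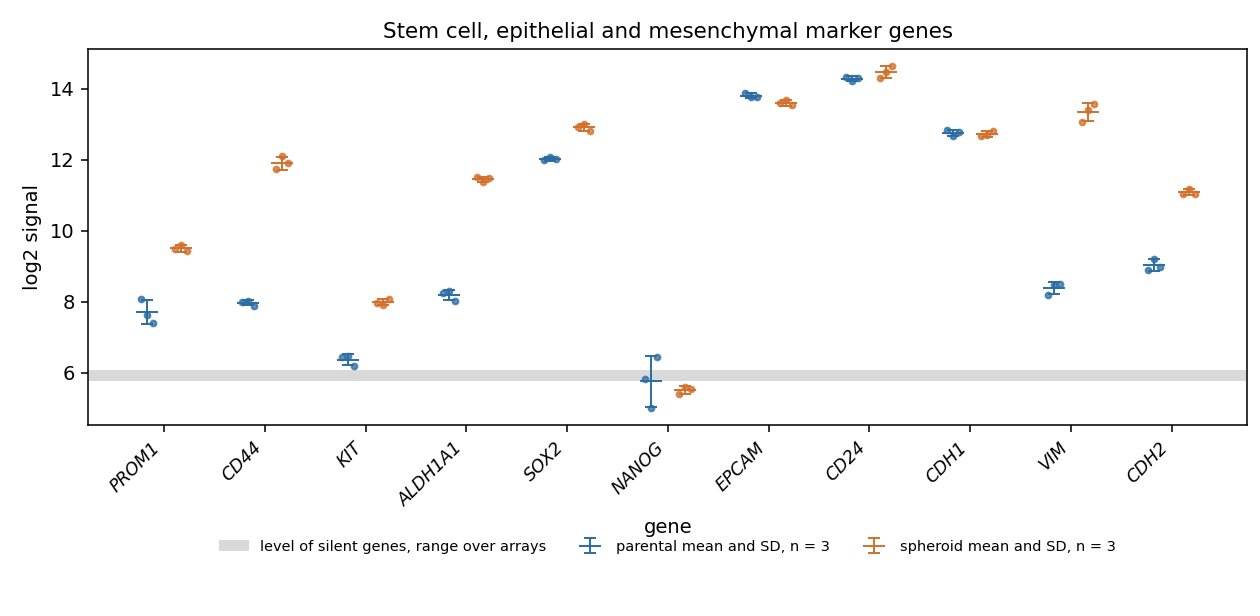
Log2 signal of 11 marker genes in each of 3 parental (blue) and 3 spheroid-derived (orange) cultures, with group means and SD as error bars; the grey band spans the level of silent genes over the 6 arrays. CD44 moved from a mean of 7.97 to 11.9 and VIM from 8.38 to 13.4, while EPCAM, CD24 and CDH1 stayed between 12.7 and 14.5 in both groups.

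Several mesenchymal genes rose, while transcripts of the epithelial adhesion molecules E-cadherin and EPCAM stayed abundant, at mean signals of 6810 and 12477 in the spheroid-derived cells. VIM, the intermediate filament vimentin, rose 31.3-fold (4.97 ± 0.14, adjusted p = 2.34e-08), from a signal of 334 to 10446. CDH2, or N-cadherin, rose 4.17-fold (2.06 ± 0.11), and S100A4, a calcium-binding protein of motile cells, rose 6.84-fold (2.77 ± 0.10). The mesenchymal list as a whole was divided. In it 10 of 24 tested members were higher and 8 lower (11 and 9 adjusted over the list alone) (camera adjusted p = 0.693). FN1, fibronectin (-1.20 ± 0.07), and THBS1, thrombospondin-1 (-3.07 ± 0.11), were among those that fell. The transcription factors SNAI2 and ZEB1 were below the level of silent genes on all 6 arrays. CDH1, which encodes E-cadherin, differed by -0.03 ± 0.07 (95% interval -0.19 to 0.13, adjusted p = 0.766), and this small value changed sign under several settings. CD24 differed by 0.18 ± 0.09 (adjusted p = 0.113) and reached 0.27 (adjusted p = 0.0251) without spheroid replicate 1. EPCAM was slightly lower (-0.21 ± 0.07, adjusted p = 0.0319), a call that was lost without parental replicate 1 (adjusted p = 0.0946), parental replicate 2 (0.0684), spheroid replicate 1 (0.0672) or spheroid replicate 3 (0.0860). Of the epithelial junction and keratin genes, 2 of 33 tested members were higher and 12 lower. The list shifted down by camera (adjusted p = 0.0112; adjusted p = 0.412 with an estimated correlation). TJP1, the tight junction scaffold ZO-1 (-1.34 ± 0.07), OCLN, the tight junction protein occludin (-0.89 ± 0.09), and GRHL1, an epithelial transcription factor (-1.33 ± 0.07), fell. KRT19, a simple epithelial keratin, rose (1.00 ± 0.11). Markers of other cell types did not pass as lists by camera. Of fibroblast and stromal markers, 2 of 5 tested members were higher and 2 lower (camera adjusted p = 0.983). Of endothelial markers, 3 of 7 tested members were higher and 0 lower (4 and 1 adjusted over the list alone) (adjusted p = 0.276). Of leukocyte markers, 2 of 8 tested members were higher and 1 lower (adjusted p = 0.817), and the median of 0.11 became -0.03 with the members near silence at their bounds. Of mesothelial markers, 2 of 6 tested members were higher and 2 lower (adjusted p = 0.998). Of neural markers, 0 of 7 tested members were higher and 3 lower (1 and 3 adjusted over the list alone) (adjusted p = 0.191).

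Large rises and falls were ranked by estimated fold among genes whose brighter mean reached the median of all tested genes, passing over symbols taken as placeholders. The largest rises by this rule were mostly of genes near silence in the parental cells, so that only lower bounds of their folds can be given. RBP4, the plasma carrier of retinol, was at least 157-fold higher, with a mean log2 signal of 13.2 ± 0.13 (SD, n = 3) in the spheroid-derived cells. WFDC21P, a whey acidic protein pseudogene, was at least 76.4-fold higher, and the glycosaminoglycan enzymes CHSY3 and CHST1 were at least 24.8-fold and at least 18.0-fold higher. Bounds were at least 18.1-fold for PIEZO2, a mechanically gated ion channel, and at least 16.1-fold for SFRP2, a secreted WNT modulator. They were at least 14.2-fold for the neuropeptide gene NPW and at least 12.1-fold for CAMP, which encodes the antimicrobial peptide cathelicidin. KRT5, the basal keratin, was below the level of silent genes on 1 of the 3 parental arrays and at least 82.6-fold higher by the same rule. ANPEP, the aminopeptidase CD13, was detected in both groups and rose 41.6-fold (5.38 ± 0.14). Among the falls were those of SOX11, an embryonic transcription factor (at least 78.6-fold lower), GPX1, a selenium-containing glutathione peroxidase (at least 26.6-fold), and SELENOP, the selenium carrier of plasma (at least 25.1-fold). Further falls were of DOK5, an adaptor of receptor tyrosine kinases (at least 20.5-fold), WNT10A (at least 16.9-fold), LRATD1 (at least 11.7-fold) and the adrenergic receptor gene ADRA2A (at least 11.2-fold). BEX1 (28.4-fold, -4.83 ± 0.15), the proteoglycan gene SPOCK2 (-4.66 ± 0.13) and FST, the activin antagonist follistatin (-4.13 ± 0.14), fell and were still detected. ZNF711 (-4.28 ± 0.12) fell more than FST but was passed over for its symbol. At least 8-fold changes were estimated for 94 genes higher and 72 lower, of which 21 and 33 had a bound under 8-fold.

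**Figure D2:**
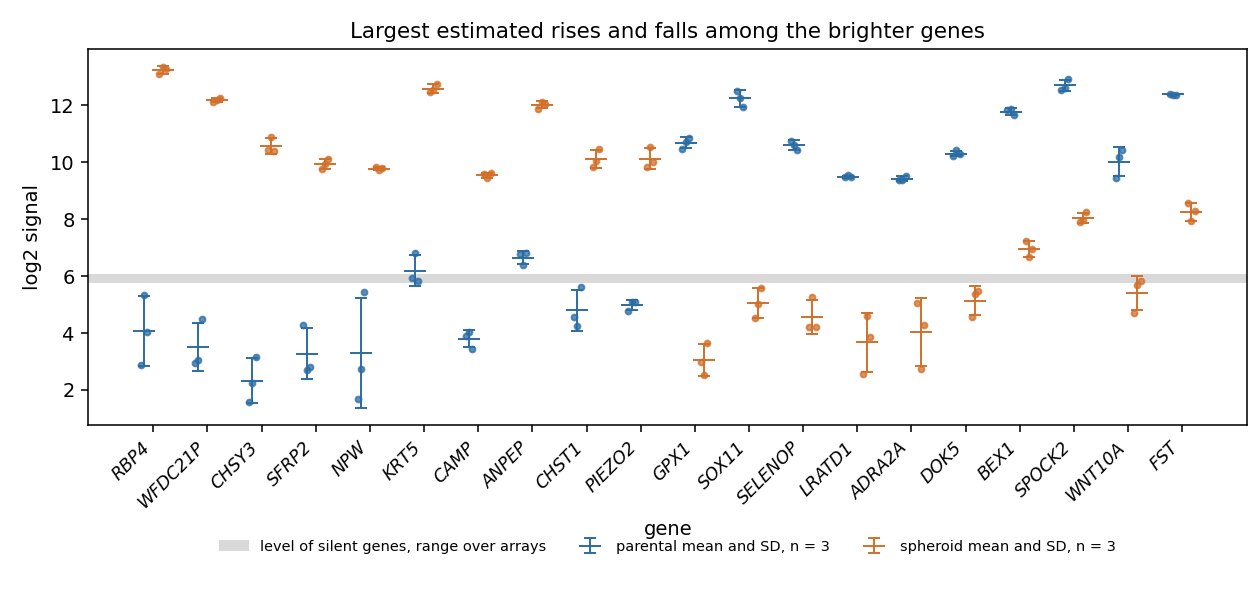
Log2 signal of the 10 genes with the largest estimated rise and the 10 with the largest estimated fall, among genes whose brighter mean reached the median of all tested genes, in each parental (blue) and spheroid-derived (orange) culture, with group means and SD as error bars and the level of silent genes as a grey band. Symbols taken as placeholders, such as those starting with ZNF, were passed over. RBP4 stood at a mean of 4.08 in parental and 13.2 in spheroid-derived cells, and GPX1 at 10.7 and 3.05.

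Of the 49 gene lists, 13 passed the camera test, 6 upward and 7 downward. None of the 49 passed with an estimated correlation between genes (smallest adjusted p = 0.412), where 4 had an unadjusted p under 0.05, and fry found all 13 to move on balance in the same direction as camera, among 33 lists that it called. The fry test compares members with no change and not with other genes, and without regard to direction it called 48 lists. Its calls for lists that camera had picked are therefore weak support. Where a list's counts adjusted over the list alone are not given, they equalled those over all genes tested. Under at least 1 alternative, 7 lists that did not pass did so: metallothionein, ribosomal protein, cholesterol synthesis, actin and SRF, G1/S, heat shock, and insulin and FOXO. Other splits of the 6 arrays into 3 and 3 gave between 3 and 11 lists past the same camera threshold. Such splits mix both kinds of culture and keep a part of the real difference, so that their counts are not a level given by chance. The median, the mean and the test differed in sign for 9 lists that did not pass: cancer stem cell markers, cell cycle inhibitors, the unfolded protein response, ERK output, laminins and matrix, estrogen response, apoptosis regulators, inflammatory cytokines and mesothelial markers.

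**Figure D3:**
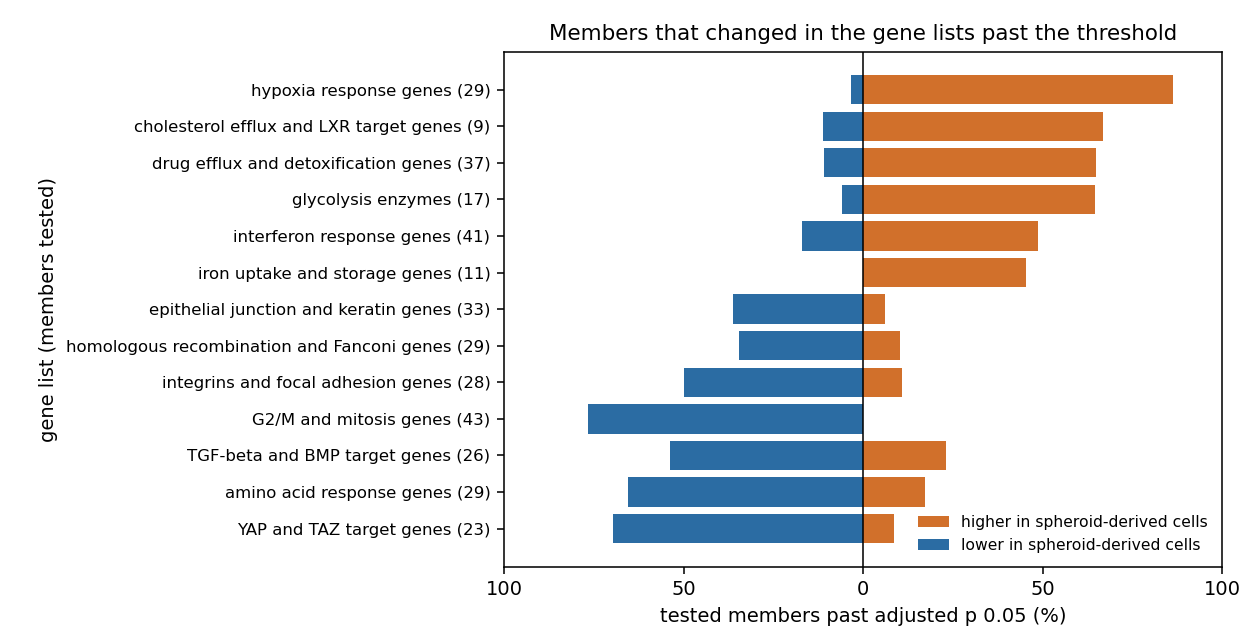
Percentage of tested members that were higher (orange, to the right) or lower (blue, to the left) in spheroid-derived than in parental cells, for the 13 lists past the camera threshold, with the number of tested members in parentheses. Of the hypoxia response genes 25 of 29 were higher, and of the G2/M genes 33 of 43 were lower.

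The list of genes that respond to low oxygen shifted upward. Of the hypoxia response list, 25 of 29 tested members were higher and 1 lower (26 and 1 adjusted over the list alone) with a median log2 fold change of 1.22 (camera adjusted p = 1.08e-09; adjusted p = 0.435 with an estimated correlation). ANGPTL4, a secreted lipase inhibitor, was at least 9.54-fold higher. PLOD2, a collagen lysyl hydroxylase, rose by 2.54 ± 0.12, and BNIP3, a mitophagy receptor, by 2.03 ± 0.11. The HIF prolyl hydroxylase gene EGLN3 fell (-1.40 ± 0.22). Of the glycolysis enzymes, 11 of 17 tested members were higher and 1 lower (12 and 1 adjusted over the list alone) (camera adjusted p = 9.10e-04; adjusted p = 0.578 with an estimated correlation). The platelet-type phosphofructokinase PFKP (2.34 ± 0.15), hexokinase HK1 (1.51 ± 0.10) and GPI, glucose-6-phosphate isomerase (0.79 ± 0.10), rose, and the muscle-type phosphofructokinase PFKM fell (-0.47 ± 0.09). Oxidative phosphorylation genes showed no shift as a list (adjusted p = 0.644). In it 15 of 45 tested members were higher and 8 lower (15 and 9 adjusted over the list alone), with rises of NDUFA2 (0.36 ± 0.06) and ATP5MC3 (0.39 ± 0.07) and falls of ATP5PD (-0.52 ± 0.06) and NDUFS4 (-1.09 ± 0.09). ATP5MC3 lay in a run of neighbouring genes that was higher as a whole, and PFKM and ATP5PD in runs that were lower. Relative to these runs the calls were lost, with differences of -0.11 for ATP5MC3 (adjusted p = 0.277), -0.13 for PFKM (0.308) and -0.17 for ATP5PD (0.0558).

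The list of mitosis genes shifted downward. Of the G2/M list, 0 of 43 tested members were higher and 33 lower (1 and 34 adjusted over the list alone) with a median of -0.48 (camera adjusted p = 1.50e-09; adjusted p = 0.412 with an estimated correlation). KIF23, a kinesin of cytokinesis (-1.33 ± 0.12), CKS2, a CDK subunit (-0.99 ± 0.07), and the centrosomal kinase NEK2 (-0.89 ± 0.08) fell. Of the G1/S and replication genes, 6 of 39 tested members were higher and 14 lower (adjusted p = 0.0657). MCM2, a replicative helicase subunit (-0.84 ± 0.08), and RFC4, a clamp loader subunit (-0.91 ± 0.08), fell. LIG1, DNA ligase I (1.40 ± 0.10), and RPA2, a single-strand binding subunit (0.70 ± 0.08), rose. Of the homologous recombination and Fanconi genes, 3 of 29 tested members were higher and 10 lower (camera adjusted p = 0.0437; adjusted p = 0.577 with an estimated correlation). This list lost its call without parental replicate 1 (adjusted p = 0.0502) or spheroid replicate 3 (0.0688), and once the shift of each run of neighbouring genes had been removed (0.145). ATR, a replication stress kinase (-0.48 ± 0.08), the helicase gene BRIP1 (-0.79 ± 0.11) and NBN, of the MRN complex (-0.73 ± 0.12), fell. RAD51B rose on the probe set used (0.81 ± 0.16) while another of its probe sets fell. Of cell cycle inhibitors, 6 of 21 tested members were higher and 5 lower (adjusted p = 0.713). TXNIP, the thioredoxin-interacting protein, was 9.14-fold higher (3.19 ± 0.07) and CCNG1 was also higher (0.63 ± 0.07). CDKN1C, which encodes p57 (-3.87 ± 0.13), and GAS1 (-2.59 ± 0.08) were lower.

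Lists of cell attachment genes and of targets of the Hippo pathway effectors shifted downward by camera. Of the YAP and TAZ targets, 2 of 23 tested members were higher and 16 lower (2 and 17 adjusted over the list alone) with a median of -0.66 (camera adjusted p = 8.24e-05; adjusted p = 0.412 with an estimated correlation). The LIM protein gene AJUBA (-2.23 ± 0.08), the angiomotin family gene AMOTL2 (-1.47 ± 0.06) and the stress gene GADD45A (-2.27 ± 0.11) fell. IGFBP3 rose (0.59 ± 0.10). Of the integrin and focal adhesion genes, 3 of 28 tested members were higher and 14 lower (camera adjusted p = 0.0417; adjusted p = 0.412 with an estimated correlation). The call of this list was lost without parental replicate 3 (adjusted p = 0.0515) or spheroid replicate 1 (0.0630). ITGB5 (-1.60 ± 0.08), ITGB1 and caveolin gene CAV1 (-1.33 ± 0.11) fell, and tensin gene TNS4 was at least 4.57-fold higher. Of the TGF-beta and BMP targets, 6 of 26 tested members were higher and 14 lower (7 and 14 adjusted over the list alone) (camera adjusted p = 0.0246; adjusted p = 0.412 with an estimated correlation). FST, ID1 (-1.44 ± 0.06) and ID2 (-2.81 ± 0.08), the last 2 inhibitors of basic helix-loop-helix factors, fell. The receptor gene TGFBR2 rose (1.76 ± 0.07). Actin and SRF target genes did not pass as a list by camera (adjusted p = 0.0657), and 1 of 24 tested members were higher and 9 lower. TPM1, a tropomyosin, was 8.04-fold lower (-3.01 ± 0.08), FHL2 was lower (-1.42 ± 0.10) and ACTA2, smooth muscle actin, was higher (1.04 ± 0.12). Of laminin and other matrix genes, 9 of 23 tested members were higher and 10 lower (adjusted p = 0.811). The collagen IV genes COL4A1 (-1.82 ± 0.09) and COL4A5 (-2.30 ± 0.11) fell, and NID2 (1.45 ± 0.08) and LAMB3 (1.59 ± 0.14) rose.

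The detoxification and interferon lists shifted upward by camera, with members in both directions. Of the drug efflux and detoxification list, 24 of 37 tested members were higher and 4 lower with a median of 0.65 (camera adjusted p = 3.92e-04; adjusted p = 0.412 with an estimated correlation). ALDH1A1 led it, with the aldo-keto reductase genes AKR1C1 (3.14 ± 0.15) and AKR1C2 (3.12 ± 0.15), near-identical paralogs whose probe sets can cross-hybridise. GSTP1, a glutathione transferase, fell (-1.48 ± 0.08). Of the NRF2 targets, 10 of 21 tested members were higher and 4 lower (11 and 5 adjusted over the list alone) (adjusted p = 0.179). The same aldo-keto reductases rose, and the cystine transporter gene SLC7A11 (-1.23 ± 0.12) and TXNRD1, thioredoxin reductase (-0.56 ± 0.07), fell. TXNRD1 differed by 0.84 (adjusted p = 0.217) with the mean of all its probe sets. Of the interferon response genes, 20 of 41 tested members were higher and 7 lower (20 and 8 adjusted over the list alone) (camera adjusted p = 0.0137; adjusted p = 0.412 with an estimated correlation). IFIT1, which binds uncapped RNA, rose 11.9-fold (3.58 ± 0.13), IFI27 9.10-fold (3.19 ± 0.12) and the ubiquitin-like ISG15 3.78-fold (1.92 ± 0.08). UBE2L6, the conjugating enzyme for ISG15, fell (-1.50 ± 0.11). Antigen presentation genes did not shift as a list (adjusted p = 0.424), and 6 of 20 tested members were higher and 1 lower (5 and 1 adjusted over the list alone). The class II pathway genes CD74 (1.50 ± 0.21) and HLA-DMB (1.73 ± 0.19) rose. B2M was lower (-0.22 ± 0.06, adjusted p = 0.0189), but not without parental replicate 1 (adjusted p = 0.0598) or parental replicate 3 (0.0525). Relative to its run of neighbouring genes it was higher (0.31, adjusted p = 0.00362). Of inflammatory and NF-kB genes, 10 of 29 tested members were higher and 9 lower (adjusted p = 0.904). The chemokine genes CXCL6 (3.45 ± 0.17) and CXCL1 (1.95 ± 0.09) rose, and the NF-kB inhibitors NFKBIA (-1.12 ± 0.07) and TNFAIP3 (-1.13 ± 0.11) fell.

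By camera the amino acid response list shifted downward, and the short lists of iron handling and cholesterol efflux genes shifted upward. Of the amino acid response list, 5 of 29 tested members were higher and 19 lower with a median of -0.54 (camera adjusted p = 4.00e-04; adjusted p = 0.412 with an estimated correlation). SLC7A5, the large neutral amino acid transporter, fell 7.94-fold (-2.99 ± 0.14), asparagine synthetase ASNS 4.43-fold (-2.15 ± 0.08) and the glycyl-tRNA synthetase GARS1 1.75-fold (-0.81 ± 0.07). CTH, of cysteine synthesis, rose (2.0 ± 0.10). Of the iron genes, 5 of 11 tested members were higher and 0 lower (camera adjusted p = 0.0311, 0.0537 without parental replicate 3; adjusted p = 0.412 with an estimated correlation). Their median log2 fold change was 0.11 and their mean 0.76, so that the shift rests on a part of the list. The ferric reductases CYBRD1 (3.84 ± 0.10) and STEAP3 (2.02 ± 0.14) and the iron exporter SLC40A1, or ferroportin (1.91 ± 0.10), rose. Of the cholesterol efflux and LXR targets, 6 of 9 tested members were higher and 1 lower (camera adjusted p = 0.0494, 0.0585 without spheroid replicate 2; adjusted p = 0.412 with an estimated correlation). The efflux transporter ABCA1 (1.17 ± 0.15), the apolipoprotein APOE (0.99 ± 0.15) and the LXR-alpha gene NR1H3 (1.05 ± 0.12) rose. MYLIP was lower (-0.27 ± 0.09, adjusted p = 0.0381), a call lost without parental replicate 1 (adjusted p = 0.110), parental replicate 2 (0.0575), spheroid replicate 2 (0.0758) or spheroid replicate 3 (0.117). Cholesterol synthesis genes were just short of the threshold (adjusted p = 0.0559), and 8 of 19 tested members were higher and 1 lower. The sterol carrier STARD4 (1.07 ± 0.10) and lanosterol synthase LSS (0.87 ± 0.09) rose. HMGCS1 was lower (-0.24 ± 0.07), though not without parental replicate 1 (adjusted p = 0.0566), parental replicate 3 (0.0680), spheroid replicate 1 (0.0713) or spheroid replicate 3 (0.0594). Metallothionein and metal genes were also just short (adjusted p = 0.0510), and 8 of 12 tested members were higher and 2 lower. MT1E (0.95 ± 0.13) and MTF1 (0.90 ± 0.12) rose. The metal importers SLC39A14 (-0.61 ± 0.08) and SLC39A8 (-0.36 ± 0.09) fell, the last with an adjusted p of 0.0530 without parental replicate 2. Of fatty acid synthesis genes, 7 of 20 tested members were higher and 5 lower (adjusted p = 0.729). ACSL1 (1.37 ± 0.11) and ELOVL5 (0.78 ± 0.08) rose, and ELOVL6 (-1.21 ± 0.09) and malic enzyme ME1 (-0.45 ± 0.09) fell. Of insulin and FOXO targets, 11 of 19 tested members were higher and 5 lower (adjusted p = 0.0657). IGFBP5 (3.37 ± 0.12) and TXNIP rose, and IGFBP2 (-2.65 ± 0.16) and the gluconeogenic enzyme PCK2 (-1.39 ± 0.11) fell.

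The WNT, NOTCH, Hedgehog, ERK and estrogen lists contained strong changes in both directions and did not pass by camera. Of WNT genes, 10 of 33 tested members were higher and 13 lower (11 and 13 adjusted over the list alone) (adjusted p = 0.729). LGR5, an R-spondin receptor and stem cell marker of the intestine, rose 16.6-fold (4.06 ± 0.16), and SFRP2 rose as given above. The ligand genes WNT11 (at least 6.0-fold lower) and WNT10A fell. Of NOTCH genes, 5 of 27 tested members were higher and 11 lower (adjusted p = 0.418). HEY1 (2.46 ± 0.10) and HES2 (1.80 ± 0.26) rose, and HEY2 (-1.52 ± 0.18) and the glycosyltransferase LFNG (-1.83 ± 0.15) fell. Of Hedgehog genes, 2 of 10 tested members were higher and 3 lower (2 and 4 adjusted over the list alone) (adjusted p = 0.424). The coreceptor gene BOC rose (1.53 ± 0.07), and GAS1, another coreceptor, and GLI3 (-1.01 ± 0.09) fell. PTCH1 was barely past the threshold (0.32 ± 0.12, adjusted p = 0.0491) and fell short of it without parental replicate 2 (adjusted p = 0.156), parental replicate 3 (0.0998), spheroid replicate 1 (0.112) or spheroid replicate 2 (0.154). Of ERK output genes, 9 of 29 tested members were higher and 7 lower (10 and 8 adjusted over the list alone) (adjusted p = 0.743). EPHA4 (1.72 ± 0.08) and the feedback inhibitor SPRY1 (1.58 ± 0.11) rose, and EGR1 (-1.97 ± 0.13) and the EGF receptor ligand HBEGF (-2.05 ± 0.15) fell. Of estrogen response genes, 4 of 17 tested members were higher and 3 lower (adjusted p = 0.817). Carbonic anhydrase CA12 (1.22 ± 0.11) and NRIP1 (0.89 ± 0.10) rose, and SIAH2 fell (-0.49 ± 0.13). Relative to its run of neighbouring genes SIAH2 was no longer past the threshold (-0.10, adjusted p = 0.599). GREB1, below the level of silent genes on 1 of the 3 spheroid arrays, was at least 2.52-fold lower.

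Lineage and secretory genes changed in both directions. Of the squamous and cornified list, 9 of 18 tested members were higher and 4 lower (adjusted p = 0.163). KRT5 and S100A8, a calprotectin subunit (3.20 ± 0.10), rose, and the keratins KRT23 (-3.95 ± 0.18) and KRT80 (-2.59 ± 0.16) fell. Its median of 0.52 became 0.29 with the members near silence at their bounds. Of ovarian carcinoma and Müllerian genes, 6 of 25 tested members were higher and 9 lower (7 and 9 adjusted over the list alone) (adjusted p = 0.729). The osteopontin gene SPP1 was at least 7.78-fold higher, and the protease inhibitor SLPI rose (1.33 ± 0.09). KLK6, a kallikrein protease (-2.44 ± 0.19), and WT1 (-1.51 ± 0.09) fell. Of mucin and secretory genes, 6 of 18 tested members were higher and 3 lower (adjusted p = 0.333). AGR2, a disulfide isomerase of mucus cells, was 5.48-fold higher (2.45 ± 0.14). MUC15 was lower (-1.04 ± 0.11), and FOXA1 was at least 2.48-fold lower. Of motile cilium genes, 1 of 15 tested members were higher and 3 lower (1 and 1 adjusted over the list alone) (adjusted p = 0.725).

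Stress, death and protein synthesis lists did not pass by camera. Of p53 targets, 8 of 21 tested members were higher and 5 lower (adjusted p = 0.729). The death receptor gene FAS (1.76 ± 0.12) and CCNG1 rose, and GADD45A and the cytokine gene GDF15 (-1.05 ± 0.20) fell. Of apoptosis regulators, 6 of 28 tested members were higher and 7 lower (adjusted p = 0.817). FAS and BCL2L11, which encodes BIM (0.50 ± 0.08), were higher, and the BH3-only genes PMAIP1 (-2.0 ± 0.12) and BID (-1.33 ± 0.09) were lower. Of heat shock chaperones, 1 of 19 tested members were higher and 7 lower (adjusted p = 0.0880). CRYAB (-1.78 ± 0.11) and BAG3 (-0.69 ± 0.07) fell, and HSPA4L rose (0.57 ± 0.13). Of unfolded protein response genes, 5 of 24 tested members were higher and 7 lower (adjusted p = 0.729). The calnexin gene CANX (0.42 ± 0.09) and DNAJB9 (0.34 ± 0.09) rose, and DNAJB11 (-0.94 ± 0.11) and MANF (-0.66 ± 0.09) fell. Of autophagy and lysosome genes, 11 of 35 tested members were higher and 8 lower (12 and 8 adjusted over the list alone) (adjusted p = 0.817). LIPA, the lysosomal acid lipase (1.29 ± 0.09), and LAMP1 (0.60 ± 0.07) rose, and the cathepsin gene CTSB (-0.91 ± 0.06) and UVRAG (-0.92 ± 0.08) fell. Of ribosomal protein genes, 3 of 25 tested members were higher and 0 lower (2 and 0 adjusted over the list alone) (adjusted p = 0.0512). Of ribosome biogenesis and MYC target genes, 4 of 29 tested members were higher and 6 lower (adjusted p = 0.904). PES1 (0.67 ± 0.10) and MRTO4 (0.93 ± 0.18) rose, and ornithine decarboxylase ODC1 (-0.62 ± 0.07) and NAMPT (-0.45 ± 0.09) fell. MRTO4 lay in a raised run of neighbouring genes and lost its call relative to it (0.37, adjusted p = 0.145).

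Neighbouring genes shifted together along parts of several chromosomes. Placed in the gene order of the reference annotation GRCh38.p14, 13576 tested genes formed 273 runs of 47 to 53 genes. In 41 of these runs, 17 higher and 24 lower, with 15.0% of the placed genes, the median log2 fold change lay over 0.33 from that of all genes. In 95% of 1000 shuffles of gene positions no run lay that far. The largest distance was 0.61, where the highest of the shuffles gave 0.44 (permutation test, two-sided, p = 0.001, the smallest possible). On chromosome 15, 238 genes from LINC01193 to AAGAB had a median of -0.51 (95% bootstrap interval -0.61 to -0.42), and 83.6% of them lay on the lower side. This interval and those that follow resample the genes of a block and carry no spread between cultures. The blocks were picked for their medians, so that the intervals and this share do not test the shift. On chromosome 2, 200 genes from SFT2D3 to KCTD18 had a median of 0.41 (0.34 to 0.49). Adjacent stretches of chromosome 17 moved in opposite directions. The 101 genes from AOC2 to HOXB9 had a median of 0.38 (0.26 to 0.46), and the next 101, from HOXB13 to LOC729683, had -0.41 (-0.53 to -0.30). Blocks of 3 runs were lower on chromosome 8 from TOX to EIF3E (-0.42), on chromosome 9 from GADD45G to GPR21 (-0.38) and at the end of chromosome 17 (-0.41). They were higher on chromosome 1 from ARHGEF19 to SNRNP40 (0.48) and chromosome 19 from ZNF224 to CLEC11A (0.48). The runs' medians had an SD of 0.21 between the groups and 0.07 between 2 replicates of a group. Among the genes named above, TPM1, THBS1, TJP1, B2M and CA12 lay in the lowered part of chromosome 15, NBN and HEY1 in that of chromosome 8, and CYBRD1, SLC40A1 and ATP5MC3 in the raised part of chromosome 2. Relative to their runs, TPM1 (-2.54), THBS1 (-2.63) and TJP1 (-0.90) were still lower, and CYBRD1 (3.33) and SLC40A1 (1.57) still higher. Some named genes rose within lowered runs, among them CA12 (1.69 relative to its run), HEY1 (3.07), PLOD2 (2.93), ABCA1 (1.58), KLF4 (0.81) and PTCH1 (0.72). NBN was no longer past the threshold (-0.12, adjusted p = 0.467), nor were PFKM, ATP5PD, ATP5MC3, SIAH2 and MRTO4. Outside the shifted runs, DNAJB9 (0.18, adjusted p = 0.124), HMGCS1 (-0.07, 0.490) and MYLIP (-0.19, 0.135) also lost their calls.

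**Figure D4:**
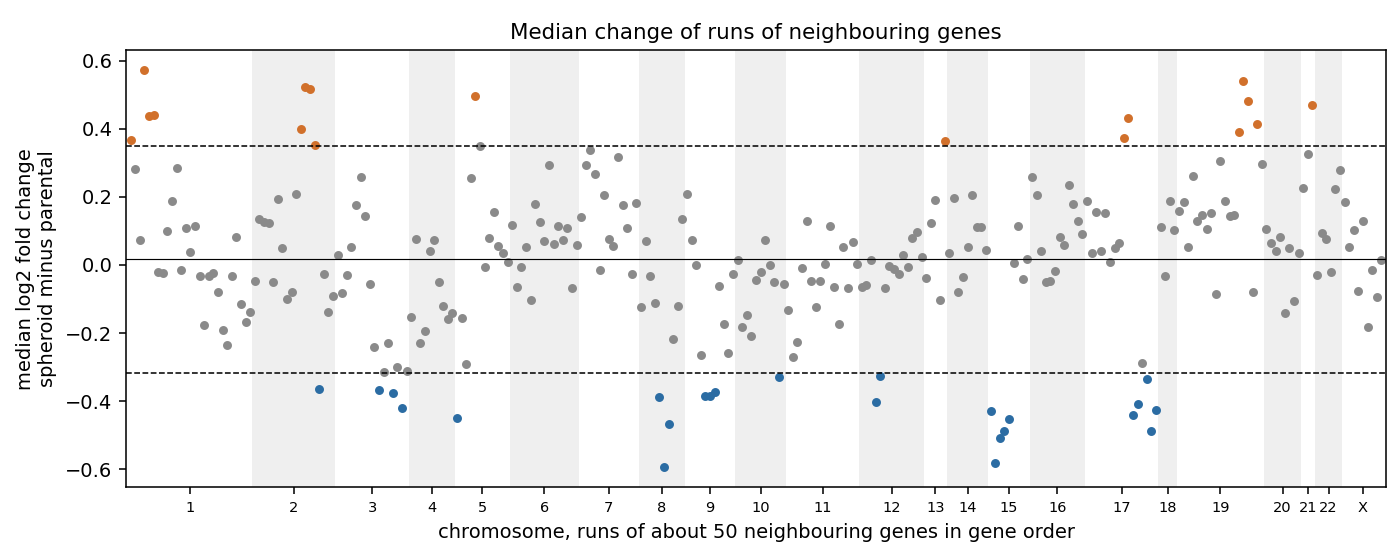
Median log2 fold change, spheroid minus parental, of 273 runs of about 50 neighbouring genes in chromosome order; orange and blue points are the 41 runs beyond the dashed lines, which lie 0.33 above and below the median of all genes (solid line). The 5 adjacent runs from LINC01193 to AAGAB on chromosome 15 lay between -0.58 and -0.43, and 4 adjacent runs on chromosome 2 between 0.35 and 0.52.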

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

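Probe sets without a usable gene name stayed outside the comparisons of genes and also differed between the groups. Of 4897 such probe sets with no gene symbol past the dimness filter, 222 were at least 2-fold higher in spheroid-derived cells and 174 at least 2-fold lower (limma over all probe sets past the filter, adjusted p under 0.05). Of 1230 probe sets with several gene symbols, 60 were at least 2-fold higher and 61 lower. Single samples far from the rest of their group were not searched for, since each group has 3 arrays.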

How the results depend on the processing

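The alternatives were fixed before the data were examined, except regional centring. Counts of changed genes stayed within 1.5 times of 6046 (range 4714 to 6461, and 5139 to 5586 without 1 array in turn; higher 2576 to 2875, lower 2463 to 2748), as did those at least 2-fold changed (1569 to 1652 without 1 array; higher 811 to 927, lower 725 to 774), with these exceptions, which follow from fewer or other tests: 484 at least 2-fold lower genes with the filter at the 60th percentile, 11600 probe sets (6079 higher, 5521 lower) when all probe sets were tested, and 631 genes (357 higher, 274 lower) with treat above 1 on the log2 scale. Centring at the 75th percentile moved the median of all genes from 0.02 to -0.06 and the share of higher calls from 51.1% to 42.6%. Robust eBayes was not run for the lists. Under regional centring 4514 of the 6046 calls stayed past the threshold in the same direction, and 18 reversed past it. Calls that kept their direction but fell short of the threshold are in neither count.

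All 13 lists kept their direction, and passed with quantile normalization, 75th percentile centring, the offset and array weights. Adjusted p values past 0.05 were 0.0627 without a filter and 0.0740 with the 60th percentile filter for cholesterol efflux; 0.0717 for integrins with the mean of all probe sets; without _x_at probe sets 0.0682 for cholesterol efflux, 0.0661 for iron and 0.0506 for homologous recombination; without a trend 0.0560 for cholesterol efflux, iron, TGF-beta and homologous recombination and 0.0583 for integrins; and 0.145 for homologous recombination with regional centring. With an estimated correlation all 13 lost their call, at 0.412 for 10 lists, 0.435 for hypoxia, 0.578 for glycolysis and 0.577 for homologous recombination. Without 1 array in turn the adjusted p ranged from 2.25e-12 to 3.68e-09 for hypoxia, 2.71e-10 to 1.46e-08 for G2/M, 4.68e-05 to 1.93e-04 for YAP and TAZ, 1.25e-04 to 6.17e-04 for drug efflux, 2.11e-04 to 8.70e-04 for amino acid response, 4.16e-05 to 0.00315 for glycolysis, 0.00241 to 0.0308 for epithelial junctions, 0.00950 to 0.0217 for interferon, 0.0137 to 0.0330 for TGF-beta, 0.0170 to 0.0537 for iron (parental replicate 3), 0.0171 to 0.0630 for integrins (parental replicate 3 and spheroid replicate 1), 0.0275 to 0.0688 for homologous recombination (parental replicate 1 and spheroid replicate 3) and 0.0235 to 0.0585 for cholesterol efflux (spheroid replicate 2). The causes were not tested.

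Calls were gained by 7 lists. Metallothioneins passed with quantile normalization (adjusted p = 0.0370), 75th percentile centring (0.0490), no filter (0.00831), array weights (0.0431) and without parental replicate 1 (0.0365), parental replicate 2 (0.0489), spheroid replicate 2 (0.0407) or spheroid replicate 3 (0.0499). Cholesterol synthesis passed with quantile normalization (0.0370), no filter (0.0197), array weights (0.0400), the replicate block (0.0480), regional centring (0.0246) and without spheroid replicate 3 (0.0340). Ribosomal proteins passed with no filter (0.0227), array weights (0.0198), the block (0.0480) and without parental replicate 1 (0.0171), spheroid replicate 1 (0.00101) or spheroid replicate 2 (0.0431). Actin and SRF targets passed with no filter (0.0380), the mean of all probe sets (0.0175), array weights (0.0431) and without parental replicate 1 (0.0291) or spheroid replicate 3 (0.0340). G1/S passed with no filter (0.0336), regional centring (0.0317) and without spheroid replicate 1 (0.0258), heat shock with quantile normalization (0.0458), no filter (0.0455) and regional centring (0.0176), and insulin and FOXO with quantile normalization (0.0458) and no filter (0.0227).

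Of 3117 values of the 175 named genes under alternatives, 3053 kept direction and side, 54 lost the call, 2 gained it and 8 reversed. The 54 lost calls, which leave out reversed values, fell on 23 genes. With the mean of all probe sets 18 lost it: PTCH1 (adjusted p = 0.450), ABCA1 (0.305), ATP5PD (0.0953), ATR (0.447), B2M (0.198), CANX (0.240), CD74 (0.0616), DNAJB9 (0.279), HMGCS1 (0.151), KRT19 (0.348), LIPA (0.596), ME1 (0.419), MYLIP (0.355), NAMPT (0.0628), NBN (0.0612), NDUFA2 (0.497), RAD51B (0.589) and SLC39A14 (0.0535). Under regional centring 8 did, named with the runs, and ATP5MC3 reversed to a value short of the threshold. Without a trend 3 did, EPCAM (0.102), B2M (0.0752) and MYLIP (0.0772), and without a filter EPCAM (0.0591) and PTCH1 (0.0669). PTCH1 also lost it with quantile normalization (0.122), 75th percentile centring (0.127), robust eBayes (0.0531) and the replicate block (0.0532). Losses without 1 array are given with EPCAM, B2M, MYLIP, HMGCS1, PTCH1 and SLC39A8. CD24 gained a call with the mean of all probe sets (0.35, adjusted p = 0.00541) and without spheroid replicate 1. The reversals were CDH1 (0.022 with quantile normalization, 0.33 with the mean of all probe sets, and from -0.075 to 0.0062 without 1 array in turn), NANOG (0.023 with array weights, and from -0.62 to 0.10 without 1 array in turn), TXNRD1 (0.84, mean of all probe sets), and under regional centring ATP5MC3 (-0.11) and B2M (0.31, adjusted p = 0.00362). The cause was not tested. Same-numbered arrays of the groups deviated together at r = 0.07, 0.04 and 0.17, so the numbers were not taken as pairs; 4 of 6 arrays correlated best with their own number. With the replicate block 6424 genes and 15 lists passed, all 13 among them. Signal near the level of silent genes limits the folds of 122 changed genes in parental and 144 in spheroid-derived cells.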

Other observations

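Several further gene groups were picked out after their values were seen and tested on the same data. Fisher's exact test takes genes as independent, whereas neighbouring genes shifted together in these data. For both reasons its p values below do not measure chance. Genes of the X chromosome made up 13.9% of the genes estimated at least 8-fold lower (10 of 72) and 3.27% of the other placed genes (Fisher's exact test, two-sided, odds ratio 4.78, 95% interval 2.17 to 9.47, p = 1.26e-04, adjusted p = 5.02e-04 over 4 such tests). Among the genes that reached 8-fold lower by measured fold or bound they were 4 of 39, past no threshold (odds ratio 3.35, 95% interval 0.860 to 9.42, adjusted p = 0.0791), so that the excess rests partly on estimates near silence. The 10 were BEX1, ZNF711, CHRDL1, ARMCX2, PWWP3B, TMEM255A, SSX1, NUDT11, DCAF12L1 and the pseudogene H2BW4P, of which the last 6 named lay near the level of silent genes in spheroid-derived cells. Among the genes at least 8-fold higher, 2 of 94 were X-linked (adjusted p = 0.772; 2 of 73 by measured fold or bound, adjusted p = 1), and no run of about 50 neighbouring genes on the X chromosome was past the limit. Smaller groups of neighbours were not tested. Zinc finger genes named ZNF accounted for 0 of 247 genes at least 4-fold higher, against 3.07% of the others (Fisher's exact test, adjusted p = 0.00198; 0 of 212 by measured fold or bound, adjusted p = 0.0135), and for 8 of 186 genes at least 4-fold lower (adjusted p = 0.369; 4 of 140 by measured fold or bound, adjusted p = 1).

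Selenoprotein genes were looked at because GPX1 and SELENOP were among the large falls. Of 20 tested, 6 were lower, 5 higher and 9 not past the threshold, with a median log2 fold change of -0.05. SELENOT (-0.80), SELENOW (-0.54) and SELENOH (-0.47) also fell, and GPX3 (1.90), GPX4 (0.75) and SELENOO (0.53) rose. Single genes outside the named set, chosen after their values were seen and forming no tested group, included ALDH2, a mitochondrial aldehyde dehydrogenase, which rose 18.0-fold, and the ephrin receptor gene EPHA3, which rose 20.8-fold. Below the level of silent genes on 2 of the 3 parental arrays, S100A9, the partner of S100A8 in calprotectin, was at least 19.6-fold and the VEGF receptor gene KDR at least 8.99-fold higher. Below it on all 3, MMP1, a collagenase, was at least 12.2-fold and PPARG, an adipocyte regulator, at least 7.73-fold higher. ID3 and ID4 fell 8.51-fold and 4.96-fold alongside ID1 and ID2.

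For the runs of neighbouring genes that shifted together, the comparison with shuffled positions and the remark on another cell line were written after the runs had been seen, and the other tests before their results were. Scatter by chance is argued against by the largest distance of 0.61 against at most 0.44 in 1000 shuffles, error of single arrays by a correlation of 0.887 between run medians of 1 pair of arrays and of the other 4, and trends with gene length or signal by the 90.2% and 87.8% of shifted runs that stayed past the limit once each trend was removed. Leaving out genes changed at least 2-fold kept 70.7%, between the bounds set beforehand, so that this test did not decide on a part played by strongly changed genes. The quartile of genes that moved least was displaced by 95.5% of the median's displacement, and the quartile that moved most by 104%. These values argue against a few strongly changed genes as the only source. A different copy number of these stretches in the spheroid-derived cells is a candidate explanation: it predicts a shift of nearly all their genes, and the quartile of genes that moved least was displaced by 95.5% of the median's displacement, above the 48.9% to 88.4% that picking the most displaced runs gave in 100 shuffles; this test took the place of a simpler one, on the direction of dim and bright genes, whose result had been seen and was fixed by the choice of runs. Regional gene regulation may give the same picture, DNA was not measured, and cells of another line cannot be told apart from these changes without arrays of one as a scale (highest correlation between a spheroid and a parental array 0.924).

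For the higher mesenchymal genes VIM, CDH2, LOX (3.82 ± 0.23) and TWIST1 (2.52 ± 0.12), the last 2 chosen after their values were seen, both tests were chosen after the result was seen. Scaling of the arrays, as a factor common to genes of similar signal, was examined in the 500 genes nearest in mean signal to each of the 4. Their medians were at most 0.10 (TWIST1, highest upper end of the 95% intervals 0.14), so that genes of similar signal did not rise with the 4. Every array had been scaled to a common mean, and the median of all tested genes was 0.02. Medians as large as these rises could therefore hardly arise, and the test is weak evidence on scaling. This test took the place of one after quantile normalization, whose outcome was fixed by the choice of the genes. A contribution of stromal cells would need a source outside the OVCAR-3 line, from which both groups were cultured. The 15 fibroblast and stromal markers, without the dimness filter, had a median log2 fold change of 0.20 (95% interval -0.55 to 0.85), but 7 of them were below the level of silent genes on all 6 arrays, where a difference decides nothing. On at least 2 of the 3 spheroid arrays 11 of the 15 were below it. The other 4 moved apart: LUM, near silence in parental cells, was at least 2.07-fold higher, FBLN1 (1.10) and COL1A2 (0.85, adjusted p = 0.0132) rose and COL1A1 fell (-0.55). Mean log2 signals of COL3A1, COL6A3 and POSTN in the spheroid-derived cells were 4.39, 2.60 and 3.98. VIM was at 13.1, 13.4 and 13.6 on the 3 spheroid arrays. COL3A1, COL6A3 and POSTN were below the level of silent genes on all 3 spheroid arrays. Beside so bright a VIM, this argues against stromal cells rich in those collagen and POSTN transcripts as its source. LUM, FBLN1 and COL1A2 rose, so that a contribution of other stromal cells stays open. A change of the OVCAR-3 cells themselves, with culture in suspension or by selection, stays among the open explanations and is a hypothesis.

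For the number of changed genes, the test of RNA quality was chosen after the result was seen. Degradation of RNA in a group is argued against by the 3' to 5' difference, which differed by at most 0.06 between the groups (ACTB). Exchanging arrays between the groups gives 10 splits, too few for a share under 0.05: 1 of the 10, the real one, gave as many changed genes (6046, highest other 0), 1 as many genes changed at least 2-fold (1607, highest other 0) and 1 as many lists past the camera threshold (13, highest other 11). Every other split mixes parental and spheroid arrays in both of its groups. The real difference then adds to the spread within groups, so that these counts do not measure what chance gives.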
